A study of Mus musculus with 3 samples.

How the data were processed

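RNA sequencing of 3 mouse libraries was analysed, 1 from wild-type articular cartilage and 1 each from exostoses labelled Ezh2-cKO and Utx-cKO. Per the labels' protocols, libraries were made with the TruSeq RNA kit and sequenced on a HiSeq instrument. The submitters' processing notes name bcl2fastq 1.8.4, HISAT2, StringTie, edgeR and the mm10 genome build. The annotation release, the counting tool, whether strand was used and the dispersion behind the authors' test are not given in the sources used here. Without strand, antisense and overlapping genes cannot be told apart, so such genes are reported as uncertain.

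The 2 deposited tables used here each set 1 exostosis library beside the same wild-type library. Raw counts per gene were deposited by the authors as whole numbers, with at least 2 counts over the pair in each row. FPKM values by the authors equal the deposited counts divided by gene length and by the column total. The authors' log2 fold change is the log2 of the ratio of their FPKM values, and it is infinite where 1 library is at 0, as in 644 and 314 of the called genes. The authors' p-values and q-values come from their comparison of 1 library with 1 library. In the authors' deposited tables every called gene had an absolute log2 fold change of at least 1 and a q-value under 0.05, and 5581 of 20971 and 4461 of 20038 genes were called. The lists of called rows deposited beside these tables were not used.

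Wild-type counts were identical in both tables for all 19385 shared genes. A gene absent from 1 table has at most 1 count there and was set to 0, which affected 653 genes of the library labelled Ezh2-cKO and 1586 of the library labelled Utx-cKO. There were 21624 gene identifiers, of which 21494 were found in GENCODE M21. Their coordinates were the same in 79.0% and overlapped in almost all, so the deposited positions were read as mm10, counted from 1. Rows that shared a symbol (22 symbols on 45 rows) were summed, which left 21601 symbols. The exostosis libraries were 4.31 and 2.62 times as deep as the wild-type library.

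TMM factors were computed with edgeR 4.0.16 in R 4.3.3 over the 3 libraries. They were 0.951, 1.005 and 1.046 for the wild-type library and the libraries labelled Ezh2-cKO and Utx-cKO. DESeq2 1.42.0 size factors, total counts and upper quartile factors were alternatives. Ratios and intervals were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. CPM here are computed from the deposited counts and the TMM-scaled library size. A gene was measured in a comparison if it had at least 1 CPM in at least 1 of the 2 libraries. Its log2 ratio used a prior count of 2, and genes were counted by size alone at 2-fold. Printed folds are ratios of TMM-normalized CPM without a prior count. Their 95% intervals are exact (Clopper-Pearson, conditional on the sum of the 2 counts) and cover counting error only, as does the floor of 3 counts used for genes at 0. With 1 library per group no test, standard error or p-value was computed.

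Before the data were examined, 31 gene lists were fixed for skeletal tissues, signalling pathways, chromatin regulators, other cell types and RNA state. Each list is described by the median log2 ratio of its measured members and by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Another 4 lists, for fetal growth, developmental and adult muscle isoforms and embryonic globins, were added after Myh8 was seen. Genes named in the text were chosen by a rule fixed beforehand. It takes Ezh2 and Kdm6a, then 13 fixed skeletal genes from Col2a1 to Ext2. For each comparison it adds the 10 highest and 10 lowest ratios among genes with a symbol and at least 10 CPM in 1 library, and up to 4 members per list. Some genes taken by the rule are not reported here. Zc3h11a, mt-Co3, Kdm5c, Eif2s3x, Ddx3x and the Hox clusters are named outside that rule. Zc3h11a, mt-Co3 and the clusters were chosen after their values were seen, and the other 3 genes were named before theirs were.

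Comparisons with the same control were set beside 100 simulations of unchanged libraries at each of 4 levels of spread. There the control, like the exostosis libraries, was drawn from the mean CPM of the observed libraries. The steps were tested on simulated data drawn from the real means and depths, with counting noise only and 200 genes altered by known folds. It says nothing of differences between animals. For the library labelled Ezh2-cKO against wild type, over 15091 genes, 100% of genes altered 3-fold and 100% of those altered 8-fold were recovered past 2-fold. The intervals held the true fold in 95.6% of genes, and 0.531% of unaltered genes passed 2-fold. For the library labelled Utx-cKO, over 15128 genes, the shares recovered were 99.0% and 100%, with 95.5% of intervals holding the true fold and 0.677% of unaltered genes past 2-fold. Ratios correlated weakly with gene length across genes, with Spearman's rho of -0.09, -0.08 and -0.01 in the 3 comparisons. Alternatives changed the scaling, the expression filter, the prior count, the threshold, the row kept per symbol and the summary of a list. Thinning all libraries to the wild-type depth, and leaving out genes of cell type, sex-linked, mitochondrial and added muscle lists, were added after the data were seen.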

Results

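RNA was sequenced from exostoses, which are bony outgrowths with a cartilage cap, of mice in which Ezh2 or Utx was to be deleted after tamoxifen. Articular cartilage of wild-type mice of the same stated age was the control. Ezh2 is the enzyme that methylates lysine 27 of histone H3, and Utx, whose gene is Kdm6a, is a demethylase of the same residue. Per the labels, mice received tamoxifen at 100 mg/kg in 4 injections over 8 days from 4 weeks of age and were 8 weeks old. There were 3 libraries, 1 per group, so there are no replicates, and differences between animals could not be measured. Total counts over genes were 8281046 in the wild-type library, 35683468 in the library labelled Ezh2-cKO and 21732018 in the library labelled Utx-cKO. A floor of 3 counts corresponded to 0.381, 0.0836 and 0.132 CPM, that is counts scaled to library size, in these libraries. Values below are CPM after TMM scaling, and ratios carry exact 95% intervals that cover counting error only.

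The targeted genes were examined first in each library. Ezh2 (ENSMUSG00000029687; mm10 chromosome 6, 47530139 to 47595341) stood at 36.8 CPM in the wild-type library, 39.0 in the library labelled Ezh2-cKO and 31.4 in the library labelled Utx-cKO. It was 1.06-fold (95% interval 0.932 to 1.21) the wild-type level in the library labelled Ezh2-cKO, a log2 ratio of 0.08 that was -0.05 with upper quartile factors. Kdm6a (ENSMUSG00000037369; mm10 chromosome X, 18162575 to 18279936) stood at 70.2, 48.1 and 46.1 CPM in the same order, and was 1.52-fold (95% interval 1.37 to 1.69) lower than wild type in the library labelled Utx-cKO. It was also 1.46-fold (95% interval 1.32 to 1.61) lower in the library labelled Ezh2-cKO, and its level in that library was 1.04-fold (95% interval 0.966 to 1.13) that of the library labelled Utx-cKO, a log2 ratio of 0.06 that was -0.02 with upper quartile factors. Neither gene was lower in its own library alone, so groups are written as libraries labelled Ezh2-cKO or Utx-cKO, and each direction below rests on labels that these genes do not bear out. These are counts over whole genes, and which exons the deletions removed is not given in the sources used here. In the authors' deposited table Ezh2 had a log2 fold change of 0.16 and a q-value of 0.845 in the library labelled Ezh2-cKO. In the authors' deposited tables Kdm6a had -0.47 in the library labelled Utx-cKO and also -0.47 in the library labelled Ezh2-cKO, and the authors called neither gene. Kdm6a fell short of a call only by the size of its fold change, since every called gene had an absolute log2 fold change of at least 1. The sex-linked genes separated the control from both exostoses. Xist, the RNA that silences an X chromosome, had 12152 counts in the wild-type library against 12 and 8. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in the wild-type library, and Ddx3y had 3104 and 2476 in the libraries labelled Ezh2-cKO and Utx-cKO.

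**Figure D1:**
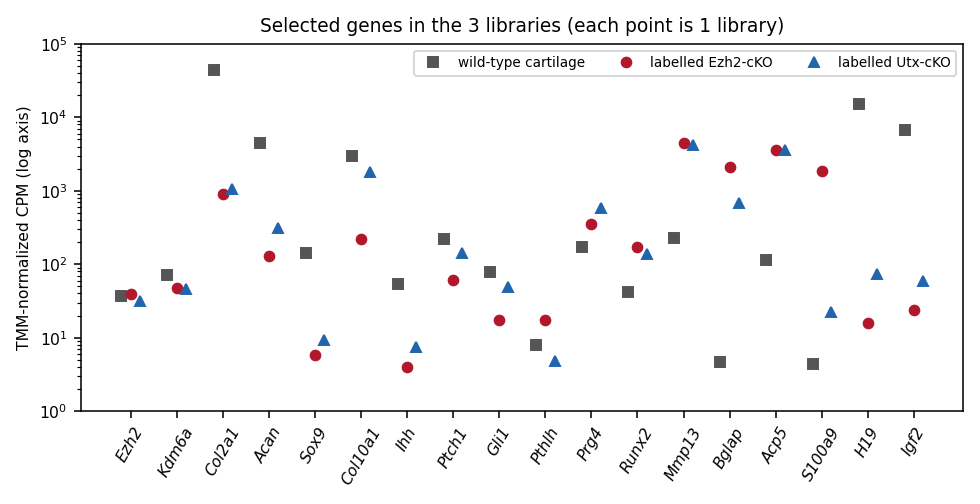
TMM-normalized CPM on a log axis for selected genes, with 1 point per library (squares, wild-type cartilage; circles, labelled Ezh2-cKO; triangles, labelled Utx-cKO). Ezh2 lay between 31.4 and 39.0 CPM in all 3 libraries, while Col2a1 was 44648 CPM in the wild-type library and 895 and 1059.7 CPM in the exostosis libraries.

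The first comparison asked which genes differ between an exostosis labelled Ezh2-cKO and wild-type articular cartilage. Cartilage matrix genes were lower in the library labelled Ezh2-cKO, and genes of osteoblasts, osteoclasts and marrow cells were higher. Col2a1, the main fibrillar collagen of cartilage (mm10 chromosome 15, 97975602 to 98004695), was 44648 CPM in the wild-type library and 895 in the library labelled Ezh2-cKO, 49.9-fold (95% interval 49.3 to 50.5) lower. Acan, the large aggregating proteoglycan, was 34.4-fold (95% interval 33.4 to 35.5) lower, and Sox9, the transcription factor that drives chondrocyte identity, was 24.4-fold (95% interval 21 to 28.4) lower. Bglap, which encodes osteocalcin of mature osteoblasts, was 4.70 and 2112 CPM, and can share reads with its close copies Bglap2 and Bglap3, so its fold is uncertain. Mmp13, a collagenase of hypertrophic cartilage and bone, was 19.7-fold (95% interval 18.8 to 20.6) higher, at 4415 CPM.

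All 18 measured cartilage matrix genes were at least 2-fold lower in the library labelled Ezh2-cKO, with a median log2 ratio of -5.08 (percentile 0 among 10000 matched random lists). The collagen IX genes Col9a1 and Col9a3 were 285-fold and 224-fold lower, and Ucma, a matrix protein of resting chondrocytes, was 396-fold lower. Matn1, a cartilage matrilin, had 13246 counts in the wild-type library and 2 in the library labelled Ezh2-cKO. Of 8 chondrocyte transcription factors, 5 were at least 2-fold lower, among them Sox5 (9.76-fold), Sox6 (16.8-fold) and Barx1 (112-fold, 95% interval 37.0 to 557). The articular surface list had 6 of 12 genes lower and 2 higher. Its members Gdf5, a joint-forming growth factor, and Cilp2 were 9.85-fold and 5.08-fold lower, while Prg4, which encodes the joint lubricant lubricin, was 2.07-fold (95% interval 1.96 to 2.19) higher. Col10a1, the collagen of hypertrophic chondrocytes, was 13.4-fold (95% interval 13.1 to 13.8) lower, in a hypertrophy list of which 7 of 16 genes were higher and 3 lower. Of these 16 genes 5 also stood in another list, so the count does not single out hypertrophic chondrocytes.

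Osteoblast and osteocyte genes were higher, 14 of 16 by at least 2-fold, with a median log2 ratio of 2.46 (percentile 100). Runx2 and Sp7, transcription factors required for osteoblasts, were 4.05-fold (95% interval 3.62 to 4.54) and 5.22-fold (95% interval 4.80 to 5.70) higher. Mepe, a matrix protein of osteocytes, was 77.7-fold higher. All 12 osteoclast genes were higher (median log2 ratio 3.87), with Acp5, the tartrate-resistant phosphatase, 31.8-fold higher and Mmp9 21.2-fold higher. Markers of marrow and blood stood beside these groups. All 15 neutrophil genes were higher (median log2 ratio 9.04, or 8.74 with genes at 0 set to the floor of 3 counts). Ngp, a neutrophil granule protein, was 1.91 CPM in wild type and 1535 CPM in the library labelled Ezh2-cKO. Of 11 B lymphocyte genes 10 were higher (median 4.36), as were 9 of 9 T lymphocyte genes (median 4.04, or 3.77 at the floor). The macrophage list had 11 of 12 genes higher (median 2.32), and the erythroid list 6 of 12 (median 2.27). Summed over members, macrophage genes were 585 CPM in wild type and 4778 in the library labelled Ezh2-cKO, whereas erythroid genes were 1191 and 1508 CPM.

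Ihh, the Hedgehog ligand of prehypertrophic chondrocytes, was 13.6-fold (95% interval 11.2 to 16.6) lower in the library labelled Ezh2-cKO. The Hedgehog targets Ptch1 and Gli1 were 3.63-fold (95% interval 3.41 to 3.87) and 4.51-fold (95% interval 4.03 to 5.04) lower, and Hhip, an inhibitor that binds Hedgehog ligands, was 13.0-fold lower. Of 15 measured genes of the Hedgehog and PTHrP list 10 were at least 2-fold lower and 1 was higher, with a median log2 ratio of -1.59. The gene that was higher was Pthlh, which encodes the peptide that holds chondrocytes back from hypertrophy, at 8.00 and 17.4 CPM, 2.17-fold (95% interval 1.68 to 2.86) higher. Ext1 and Ext2, the polymerases of heparan sulphate that are mutated in hereditary multiple exostoses, were 1.68-fold (95% interval 1.56 to 1.81) higher and 1.06-fold (95% interval 0.986 to 1.14) lower.

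The genes with the highest ratio in this comparison were Chil3, Camp, mt-Nd4l, Ly6c2, Elane, Igha, Eif2s3y, Ddx3y, Hoxd13 and Igkc. Elane, a neutrophil protease, had 0 counts in the wild-type library and 4216 in the library labelled Ezh2-cKO, at least 308-fold higher. Camp, an antimicrobial peptide of neutrophils, had 1 count and 24457 counts. Igha and Igkc are immunoglobulin constant region genes, which can share reads with related genes and are uncertain. The lowest ratios were those of Myh8, Acta1, mt-Nd4, Myh4, Ckm, Mybpc1, Matn1, Atp1b4, Myh3 and Myh1, most of them genes of skeletal muscle. Myh8, the perinatal myosin heavy chain (mm10 chromosome 11, 67277124 to 67308634), had 72694 counts in the wild-type library and 1 in the library labelled Ezh2-cKO. All 17 skeletal muscle genes were lower (median log2 ratio -9.64), and they took 2.57% of the counts of the wild-type library (exact 95% interval 2.56% to 2.58%). mt-Nd4 and mt-Nd4l, which overlap by 7 bases, had 22258 and 1 counts in wild type against 0 and 17638; these counts are uncertain, and their cause was not tested.

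By size alone, 3088 genes were at least 2-fold higher and 2319 at least 2-fold lower in the library labelled Ezh2-cKO, of 15723 measured. In the authors' deposited table, 3309 genes were marked up and 2272 down. With 1 library per group these counts compare 2 libraries and not 2 conditions, and tissue, sex and depth differ along with genotype. Muscle genes took 2.57% of wild-type counts against 0.00478% here, and the added fetal growth list took 2.85% against 0.0328%. At a 4-fold threshold the counts were 1594 and 1228, and with at least 10 CPM they were 1945 and 1317.

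The second comparison set the library labelled Utx-cKO against the same wild-type library. Cartilage matrix genes were again lower and bone genes higher, while neutrophil and lymphocyte genes were closer to the wild-type level and erythroid genes were lower. Col2a1 was 1059.7 CPM, 42.1-fold (95% interval 41.6 to 42.7) lower, Acan was 14.5-fold (95% interval 14.1 to 14.9) lower and Sox9 was 15.5-fold (95% interval 13.3 to 18.0) lower. Col10a1 was 1786 CPM against 2987 in wild type, 1.67-fold (95% interval 1.65 to 1.70) lower. Ibsp, a sialoprotein of bone matrix, was 836 and 8899 CPM, 10.7-fold (95% interval 10.4 to 10.9) higher, and Mmp13 was 18.6-fold (95% interval 17.7 to 19.5) higher.

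Of 18 cartilage matrix genes 16 were at least 2-fold lower in the library labelled Utx-cKO and 2 lay within 2-fold, with a median log2 ratio of -5.13 (percentile 0). Epyc, a small proteoglycan of growth plate cartilage, was 113-fold lower, Ucma was 251-fold lower, and Matn1 had 1 count against 13246. Chondrocyte transcription factors had a median of -2.69, with 5 of 8 lower, among them Sox5 (7.81-fold), Sox6 (6.43-fold) and Nkx3-2 (7.01-fold). The articular surface list had 5 of 12 genes lower and 2 higher, and Prg4 was 3.44-fold (95% interval 3.25 to 3.64) higher. Of 16 hypertrophy genes 8 were higher and 1 was lower, with Spp1, which encodes osteopontin, 12-fold higher and Alpl, the phosphatase of mineralizing cells, 5.70-fold higher. The gene that was lower was Ihh, the Hedgehog ligand of prehypertrophic chondrocytes, and Col10a1 lay within 2-fold. Of the 16 genes 5 also stood in another list, among them Mmp13, so this count does not single out hypertrophic chondrocytes.

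Of 16 osteoblast and osteocyte genes 13 were higher in the library labelled Utx-cKO (median log2 ratio 2.04, percentile 100). Runx2 and Sp7 were 3.31-fold (95% interval 2.95 to 3.71) and 4.29-fold (95% interval 3.93 to 4.69) higher, Mepe was 59.2-fold higher, and Sost, an inhibitor of Wnt signalling made by osteocytes, was 8.31-fold higher. Of 12 osteoclast genes 10 were higher (median 3.52), with Acp5 31.4-fold and Mmp9 36.9-fold higher. Beside these groups the macrophage list had 9 of 12 genes higher (median 1.66) and the neutrophil list 8 of 12 (median 1.66). The B lymphocyte list had 2 of 3 measured genes higher (median 1.23), and the T lymphocyte list 2 of 3 (median 1.28). Of 9 erythroid genes 7 were lower and 2 were higher (median -2.90). The alpha globin gene Hba-a1, whose reads can be shared with its near-identical copy, was 229 and 28.2 CPM.

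Ihh was 7.34-fold (95% interval 6.13 to 8.83) lower in the library labelled Utx-cKO, and Ptch1 and Gli1 were 1.55-fold (95% interval 1.46 to 1.64) and 1.63-fold (95% interval 1.47 to 1.79) lower. Of 15 genes of the Hedgehog and PTHrP list 6 were at least 2-fold lower and 0 were higher (median -0.74). Pthlh was 1.68-fold (95% interval 1.21 to 2.32) lower, Ext1 was 1.73-fold (95% interval 1.60 to 1.86) higher and Ext2 was 1.17-fold (95% interval 1.08 to 1.26) higher. Grem1, a secreted inhibitor of bone morphogenetic proteins, was 14.8-fold lower.

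The highest ratios were those of mt-Nd4l, Eif2s3y, Hoxd13, Ddx3y, Lyz1, Rpl29, Uty, Kdm5d, Cyp2f2 and mt-Co2. Lyz1, a lysozyme, had 0 counts in the wild-type library and 1001 in the library labelled Utx-cKO, at least 116-fold higher. Rpl29, a ribosomal protein gene with pseudogene copies that can share its reads, had 2, 22 and 3431 counts in the wild-type library and the libraries labelled Ezh2-cKO and Utx-cKO, and is uncertain. The ratio of mt-Co2, with 0 counts in the wild-type library, is uncertain too, as are those of mt-Nd4l and mt-Nd4. The lowest were Myh8, mt-Nd4, Matn1, Myh3, Xist, Actc1, Tceal7, Atp1b4, Mybpc2 and Myh7. All 17 skeletal muscle genes were lower (median -6.90). Tceal7 had 1619 counts in wild type and 0 in both exostosis libraries, at least 1559-fold lower in the library labelled Utx-cKO.

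In total 2078 genes were at least 2-fold higher and 2400 at least 2-fold lower in the library labelled Utx-cKO, of 15289 measured. In the authors' deposited table, 2326 genes were marked up and 2135 down. These are again 2 libraries, with tissue, sex and depth differing along with genotype. The added fetal growth list took 2.85% of wild-type counts against 0.0621% here, and muscle genes took 2.57% against 0.0249%. At 4-fold the counts were 738 and 1287, with at least 10 CPM 1222 and 1273, and with no expression filter 3245 and 3695. Under total counts they were 2549 higher and 2078 lower, so the balance of directions depends on scaling.

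**Figure D2:**
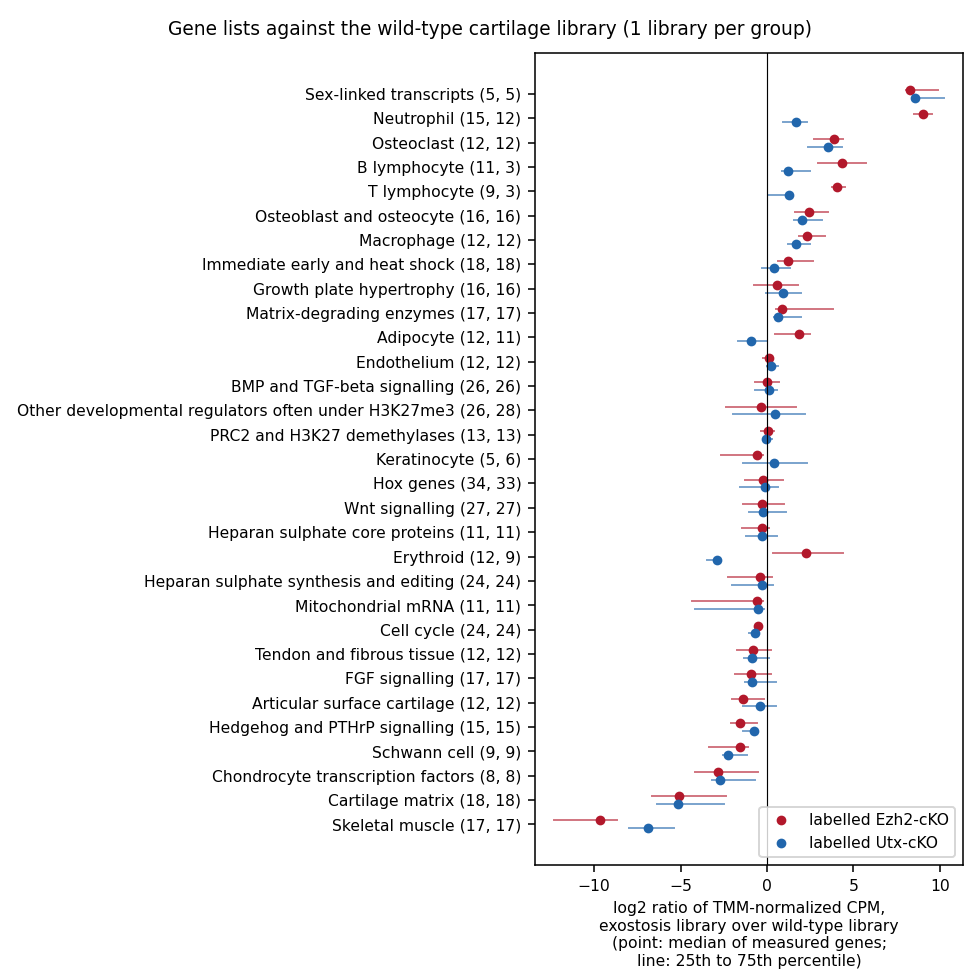
Median log2 ratio of TMM-normalized CPM (points) and 25th to 75th percentile over genes (lines) for each gene list, in the libraries labelled Ezh2-cKO and Utx-cKO over the wild-type library, with the number of measured genes in parentheses. Cartilage matrix lay at -5.08 and -5.13, osteoclast genes at 3.87 and 3.52, and erythroid genes at 2.27 and -2.90.

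Set against the same wild-type library, both exostosis libraries had higher bone and osteoclast genes and lower cartilage, muscle and Hoxc genes. Over 15101 genes measured in both comparisons, 1590 were at least 2-fold higher in both and 1831 at least 2-fold lower in both. Among these genes, independent lists of the observed 2506 and 1939 higher genes would share 322, and lists of the observed 2319 and 2400 lower genes would share 369. For the simulations all 3 libraries, the shared control included, were drawn from the mean CPM of the observed libraries. These unchanged libraries shared on average 28.7 and 21.1 with counting noise alone, and 821 and 594 with a biological coefficient of variation of 0.4. The log2 ratios correlated across genes at r = 0.876, against 0.806 and 0.533 in those simulations, and genes are not independent replicates. Their covariance was 2.59, against a simulated 0.0410 and 0.412. The control is 1 library and could not be split, so part of the excess may come from the shared control. In 51 genes the library labelled Ezh2-cKO was higher and the library labelled Utx-cKO lower than wild type, each by at least 2-fold, and 8 genes went the other way. Under total counts in place of TMM scaling, 1878 genes were higher and 1653 lower in both, so the balance of directions depends on scaling.

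Hox genes, which encode position along the body and limb axes, differed by cluster, a subdivision made after the values were seen. All 7 measured Hoxc genes were at least 2-fold lower in both exostosis libraries, with median log2 ratios of -4.95 in the library labelled Ezh2-cKO and -5.69 in the library labelled Utx-cKO. Hoxc10 (mm10 chromosome 15, 102966796 to 102971893) was 37.1 CPM in the wild-type library, 121-fold (95% interval 66.6 to 245) and 141-fold (95% interval 63.8 to 386) lower. All 4 genes from Hoxd10 to Hoxd13 were higher in both, with medians of 5.59 and 5.01. Of the other 4 measured Hoxd genes, 0 were higher and 2 lower in each comparison. Hoxd13 (mm10 chromosome 2, 74668310 to 74671599), a gene of the distal limb, had 0 counts in the wild-type library and 2936 and 2766 in the libraries labelled Ezh2-cKO and Utx-cKO, at least 215-fold and at least 319-fold higher. Hoxa13, which marks the same part of the limb, had 3, 553 and 136 counts. Measured Hoxa genes had medians of 0.03 and -0.51, with 3 of 11 and 1 of 10 higher and 1 lower in each comparison, and measured Hoxb genes had medians of 0.11 and 0.48. Over the whole Hox list 9 of 34 genes were higher and 10 lower in the library labelled Ezh2-cKO, and 5 and 10 of 33 in the library labelled Utx-cKO. Other developmental regulators that often carry the methyl mark written by Ezh2 were spread both ways, with 11 higher and 13 lower of 26 in the library labelled Ezh2-cKO, and 12 and 12 of 28 in the library labelled Utx-cKO. Pax7, a gene of muscle satellite cells, had 100 counts in wild type and 0 in both exostosis libraries, at least 152-fold lower in the library labelled Ezh2-cKO. Of 13 genes of the Polycomb complex and its demethylases 10 and 12 lay within 2-fold of wild type. In the library labelled Ezh2-cKO 2 were higher and 1 was lower, and in the library labelled Utx-cKO 0 were higher and 1 was lower. The lower gene was Phf19, an accessory Polycomb protein, at 5.48-fold (95% interval 4.19 to 7.17) and 6.81-fold (95% interval 4.90 to 9.58) lower.

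**Figure D3:**
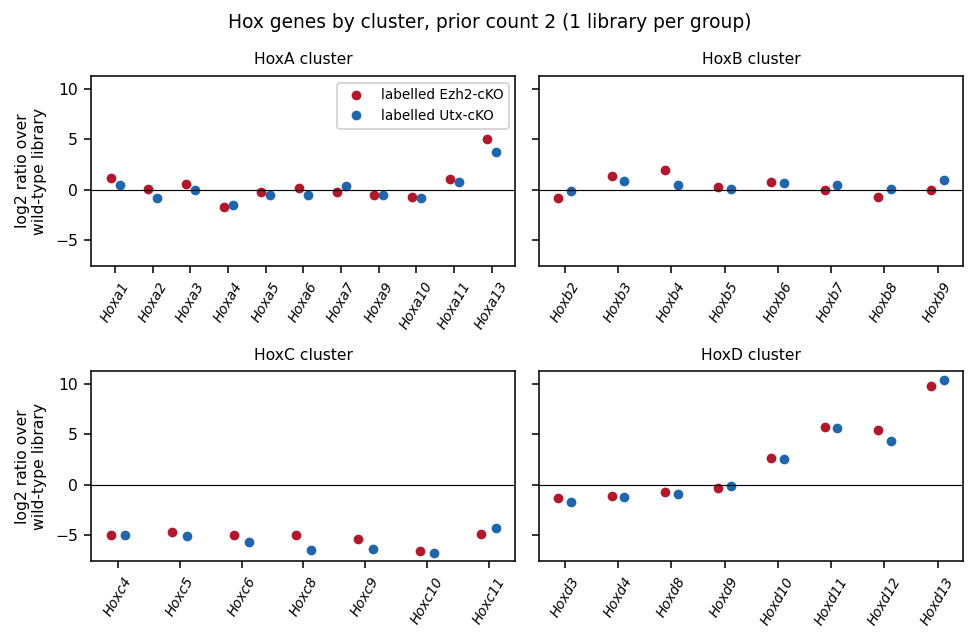
Log2 ratio over the wild-type library for each measured Hox gene, in 1 panel per cluster, with a prior count of 2, for the libraries labelled Ezh2-cKO and Utx-cKO. Hoxc10 lay at -6.55 and -6.71 and Hoxd13 at 9.83 and 10.40, where the wild-type count of 0 makes the plotted ratio depend on the prior count.

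Other signalling groups were also compared with wild type. The FGF list had a median of -0.90 in the library labelled Ezh2-cKO and -0.89 in the library labelled Utx-cKO, with 7 and 6 of 17 genes lower, and the receptor gene Fgfr4 was 151-fold and 95.7-fold lower. The BMP and TGF-beta list had medians of 0.01 and 0.12, with 17 and 15 of 26 genes within 2-fold, and Id3, a target of BMP signalling, was 5.16-fold and 4.21-fold higher. The Wnt list had medians of -0.26 and -0.24, with the secreted Wnt inhibitor Dkk1 7.77-fold and 8.28-fold higher and Sfrp5 18.6-fold and 6.70-fold lower. Of 24 genes that build and edit heparan sulphate 15 and 16 lay within 2-fold, and Hs6st2, a sulphotransferase, was 27.4-fold and 20.8-fold lower. Among heparan sulphate core proteins (medians -0.29 and -0.28) the glypican Gpc3 was 57.8-fold and 21.5-fold lower. Gpc3 is also a member of the added fetal growth list, which was lower as a whole. Matrix-degrading enzymes had medians of 0.86 and 0.62, and the stromelysin Mmp3 was 48.7-fold and 27.6-fold higher. Cell cycle genes had medians of -0.49 and -0.69, with 2 and 7 of 24 at least 2-fold lower. Cdk1, the mitotic kinase, was 2.09-fold and 2.04-fold lower.

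The third comparison set the library labelled Ezh2-cKO directly against the library labelled Utx-cKO, which leaves out the cartilage library. Genes of neutrophils, erythroid cells, lymphocytes and adipocytes were higher in the library labelled Ezh2-cKO, and muscle genes, Col10a1 and the Hedgehog targets Ptch1 and Gli1 were lower. Camp was 682 CPM in the library labelled Ezh2-cKO and 1.10 in the library labelled Utx-cKO, 620.1-fold (95% interval 420.0 to 958) higher. Slc4a1, the anion exchanger of red cells, was 275-fold (95% interval 144 to 601) higher. Col10a1 was 8.03-fold (95% interval 7.84 to 8.23) lower, Ptch1 and Gli1 were 2.34-fold (95% interval 2.22 to 2.48) and 2.77-fold (95% interval 2.51 to 3.06) lower, and Pthlh was 3.66-fold (95% interval 2.98 to 4.54) higher. Of the hypertrophy list 13 of 16 genes lay within 2-fold (median -0.20), as did 11 of 15 of the Hedgehog and PTHrP list (median -0.28).

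All 15 neutrophil genes were higher in the library labelled Ezh2-cKO (median log2 ratio 7.58), with 11 of 12 erythroid genes (median 3.95), 10 of 11 B lymphocyte genes (median 4.08), 9 of 9 T lymphocyte genes (median 3.22) and 3 of 12 macrophage genes (median 0.66). Of 12 adipocyte genes 11 were higher (median 2.47), including Adipoq, the hormone adiponectin, at 13.1-fold (95% interval 10.3 to 17.0). The osteoblast list had 3 of 16 genes higher and 0 lower by 2-fold. Ibsp, of the hypertrophy list, was 2.75-fold (95% interval 2.73 to 2.77) lower. Osteoclast genes had a median of 0.14, with 11 of 12 within 2-fold, and Acp5 had a log2 ratio of 0.02 that was -0.04 with total counts and -0.07 with upper quartile factors. Cartilage matrix genes had a median of -0.61, with 7 of 17 lower and 2 higher. Acan was 2.38-fold (95% interval 2.29 to 2.47) lower, Fmod, a small proteoglycan, was 2.62-fold lower and Epyc was 3.38-fold higher. Frzb, a secreted Wnt antagonist of cartilage, was 6.69-fold (95% interval 6.07 to 7.39) lower, and the BMP receptor gene Bmpr1b was 13.0-fold (95% interval 7.61 to 24.0) lower. Grem1 was 6.09-fold (95% interval 5.06 to 7.39) higher.

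Among the highest ratios here were those of Camp, Ngp, Ms4a3, Ltf, Itgb2l, Prg2, Elane, Cebpe and Mpo, which are genes of granulocytes and their precursors. Mpo, myeloperoxidase, was 246-fold (95% interval 164 to 388) higher. The lowest were Myh1, Rpl29, Pcdhb17, Krt2, Acta1, Myh2, Zbed6, Atp2a1, Neb and Cdsn. Krt2 and Cdsn are genes of the outer epidermis, and Krt2 had 0 counts in the library labelled Ezh2-cKO and 252 in the library labelled Utx-cKO. Zbed6 lies within Zc3h11a on the same strand, so its 37 and 1088 counts are uncertain. Of 17 skeletal muscle genes 15 were lower (median -3.56). By size 1899 genes were at least 2-fold higher and 601 at least 2-fold lower of 15015 measured, with no authors' table for this pair used here. At 4-fold there were 965 and 151, with at least 10 CPM 961 and 229, and with no filter 3028 and 1413.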

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

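Results are listed here because the libraries labelled Ezh2-cKO and Utx-cKO lay on opposite sides of wild type, each by at least 2-fold. The differences were not tested, since each group has 1 library, and the directions rest on labels that Ezh2 and Kdm6a do not bear out. The erythroid list had a median log2 ratio of 2.27 in the library labelled Ezh2-cKO and -2.90 in the library labelled Utx-cKO, over 12 and 9 measured genes. In the library labelled Ezh2-cKO 6 of these 12 erythroid genes lay within 2-fold, and the summed list was 1191, 1508 and 550 CPM in the wild-type library and the libraries labelled Ezh2-cKO and Utx-cKO. Its member Slc4a1, the anion exchanger of red cells, stood at 4.36 and -3.45. The adipocyte genes Adipoq and Cidec, a lipid droplet protein, stood at 2.58 and -1.10 and at 1.91 and -2.25. Lck, a kinase of T lymphocytes, stood at 1.94 and -1.18. Panx3, a channel of prehypertrophic cartilage and osteoblasts, went the other way, at -1.17 and 1.15, as did Zbed6, at -2.46 and 2.95, whose counts are uncertain because it lies within Zc3h11a.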

How the results depend on the processing

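Thinning to the wild-type depth and leaving out cell type, sex-linked, mitochondrial and added muscle list genes were chosen after the data were seen, and the other alternatives were planned. The DESeq2 factors, total counts, upper quartile factors, prior counts of 0.5 and 10, the row with the most counts per symbol and both added alternatives kept all 8 counts of genes within 1.5 times their values. Leaving out the list genes took measured genes only from 15723 to 15560 in the library labelled Ezh2-cKO against wild type. So few genes could not have moved any count past that bound, so this alternative does not show that the counts are free of other tissues or sex. A 4-fold threshold gave 1594 higher and 1228 lower in the library labelled Ezh2-cKO, 738 and 1287 in the library labelled Utx-cKO, 965 and 151 between them, and 547 and 981 shared. A filter of 10 CPM gave 1945 and 1317, 1222 and 1273, 961 and 229, and 952 and 1003 in the same order. No filter beyond 1 read moved the counts for the library labelled Utx-cKO to 3245 and 3695 and those between the exostoses to 3028 and 1413. These follow from a stricter threshold or from fewer or more genes. Total counts shifted the median of all genes by 0.14 in the library labelled Utx-cKO, and upper quartile factors by -0.13 in the library labelled Ezh2-cKO. The share of higher genes among those apart moved from 46.4% to 55.1% under total counts in the library labelled Utx-cKO and from 57.1% to 51.6% under upper quartile factors in the library labelled Ezh2-cKO. No list or named gene at least 2-fold apart changed sign under the alternatives run. Ezh2 in the library labelled Ezh2-cKO moved from 0.08 to -0.05 under upper quartile factors. Kdm6a between the exostoses moved from 0.06 to -0.02 under the same factors. Medians under 1 in size of the Polycomb, BMP, endothelium, Hox, heparan sulphate synthesis, developmental regulator, chondrocyte factor, matrix enzyme and developmental muscle lists changed sign under at least 1 alternative in 1 or more comparisons. The pseudocount planned for normalized values was not run because counts were present. No paired analysis was possible because the results come from no test with 1 library per group. Depth limits the wild-type library most, where 3 counts are 0.381 CPM.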

Other observations

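The test of exchanged labels and the 4 added lists were chosen after the pattern was seen, and the other tests were written before their values were. Tissue around the skeleton also differed from wild type. Schwann cell genes were lower in both exostosis libraries, 7 of 9 in the library labelled Ezh2-cKO (median log2 ratio -1.57) and 9 of 9 in the library labelled Utx-cKO (-2.26). Tendon and fibrous tissue genes had medians of -0.80 and -0.84. Tnmd, a tendon membrane protein, was 35.3-fold and 11.5-fold lower, while the keratan sulphate proteoglycan Lum was 5.20-fold and 4.21-fold higher. Endothelial genes stayed near wild type, with medians of 0.11 (-0.02 with upper quartile factors) and 0.26. Adipocyte genes had medians of 1.87 and -0.89, and keratinocyte genes, of which 5 and 6 of 12 were measured, had -0.58 and 0.38. Of the neutrophil, erythroid and B lymphocyte lists, 5 of 15, 8 of 13 and 2 of 12 genes had at least 1 CPM in the wild-type library, and 1 neutrophil gene stood in another list. S100a9, a calcium-binding protein of neutrophils, was 1829.9 CPM in the library labelled Ezh2-cKO and 22.2 in the library labelled Utx-cKO. Among the added lists, developmental muscle isoforms had medians of -7.28 and -6.60 (-7.33 and -6.32 with genes at 0 set to the floor), adult fast muscle isoforms had -10.97 and -6.90, and no embryonic globin was measured.

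Immediate early and heat shock genes, which can respond to handling, had a median of 1.20 in the library labelled Ezh2-cKO, 0.42 in the library labelled Utx-cKO and 1.44 between them. Fos and Egr1, transcription factors induced within minutes of a stimulus, were 3.61-fold (95% interval 3.47 to 3.77) and 3.98-fold (95% interval 3.80 to 4.18) higher in the library labelled Ezh2-cKO than in the library labelled Utx-cKO. Mitochondrial mRNAs had medians of -0.56 and -0.50 against wild type, and these medians are uncertain, since 4 of the 11 measured genes, mt-Nd3, mt-Nd4, mt-Co2 and mt-Co3, were at 0 in a library of each comparison. mt-Co2 had 0, 1008 and 550 counts in the wild-type library and the libraries labelled Ezh2-cKO and Utx-cKO, which are uncertain. The sum of mt-Nd4 and mt-Nd4l was 2827 CPM in wild type and 492 and 481 CPM in the exostosis libraries. Of the sex-linked list 4 of 5 genes were higher in each exostosis library and Xist was lower.

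Myh8, a perinatal myosin, was among the most abundant genes of the wild-type library, whose label gives an age of 8 weeks. Adult muscle carried over with the cartilage would bring mostly Myh1, Myh2 and Myh4. These took 24.0% of 102658 counts over 5 myosin genes (exact 95% interval 23.7% to 24.2%). That is under the bound of 50 set before the share was computed. Myh8, already seen to be abundant, is among the 5 genes, so the low share was not an independent prediction. It goes against adult muscle as the only source. Myh1, Myh2 and Myh4 still had 24618 counts, so adult muscle as part of the source stays open. Genes of fetal and perinatal growth, of which 13 of 14 had at least 1 CPM in the wild-type library and 1 stood in another list, were lower in both exostosis libraries, with medians of -4.70 in the library labelled Ezh2-cKO and -4.42 in the library labelled Utx-cKO, each at percentile 0. H19 and Igf2, imprinted genes of fetal growth, were 15128 and 6708 CPM in the wild-type library and 74.1 and 59.8 in the library labelled Utx-cKO. These values are consistent with tissue younger than the label states, as a hypothesis, while regenerating muscle and a difference between tissues stay open and were not tested.

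Cartilage matrix genes were lower in both exostosis libraries. A lower share of chondrocytes alone would lower these genes by one factor only if no other cells expressed them, which was not tested. Their log2 ratios had an interquartile range of 3.89 or more in both comparisons, so this range does not decide the question. Scaling was argued against, since the median stayed at -4.99 or lower under the other scalings run. Marrow and blood cells in both exostosis libraries were predicted to raise the erythroid list in each, but its median was -2.90 in the library labelled Utx-cKO. Erythroid genes summed to 1191 CPM in wild type and 550 there, so that ratio depends on the control and does not exclude marrow cells. The neutrophil, B lymphocyte and macrophage medians there were higher, at 1.66, 1.23 and 1.66 over 12, 3 and 12 measured genes. The medians of all 4 lists in the library labelled Ezh2-cKO were higher too. In the wild-type library and the libraries labelled Ezh2-cKO and Utx-cKO, neutrophil genes summed to 14.6, 8174 and 54.2 CPM. In the same order B lymphocyte genes summed to 58.1, 410 and 95.3 CPM, and macrophage genes to 585, 4778 and 2344 CPM. Hoxc genes and Hoxd10 to Hoxd13, which encode position, also separated the control from both exostoses, and a difference in body site was not tested. A lower share of chondrocytes could contribute to the pattern. So could a difference between articular cartilage and exostosis, between sexes, stages or body sites, or from the genotype. The design does not separate them.

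Ezh2 was not lower in the library labelled Ezh2-cKO, where it stood at 1.24-fold (95% interval 1.13 to 1.36) the level of the library labelled Utx-cKO, the direction an exchange of labels would give. An exchange would also make Kdm6a lower in the library labelled Ezh2-cKO than in the library labelled Utx-cKO, but it stood at 1.04-fold there. An exchange cannot be told apart from the labels as given, since Ezh2 at 0.854 of wild type (lower bound 0.744) in the library labelled Utx-cKO shows no 2-fold loss, and neither do Ezh2 and Kdm6a in their own libraries. Dividing cells of other types as the source were predicted to raise the cell cycle list over wild type, but its median was -0.49 in the library labelled Ezh2-cKO. The control had high fetal growth genes and may itself hold dividing cells, so this ratio cannot decide the question. The cell cycle median of 0.22 over the library labelled Utx-cKO goes with such cells. For Kdm6a, which was lower in both, a female control could contribute, since Kdm5c and Eif2s3x, which also escape X inactivation, were at 0.663 and 0.632 of wild type in the library labelled Ezh2-cKO and 0.618 and 0.743 in the library labelled Utx-cKO. Ddx3x, at 0.974 and 1.08 (95% interval 1.04 to 1.11) in the same order, goes against this. The median over these 3 genes was at most 0.743 over both comparisons, so against wild type alone sex and deletion cannot be told apart. Both exostosis libraries had counts of Y-linked genes, and Kdm6a differed between them by only 1.04-fold (95% interval 0.966 to 1.13). On the labels as given, Utx was not targeted in the library labelled Ezh2-cKO, so a Utx deletion would not account for the fall there. Similar folds in 1 library each do not show a common cause. A Utx deletion therefore stays open for the library labelled Utx-cKO. Unexcised cells or transcripts that keep the undeleted exons stay open.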
